A study of Homo sapiens with 6 samples.

How the data were processed

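Gene expression was measured in MOLM-14, an established human acute myeloid leukaemia cell line that carries an MLL-AF9 rearrangement. Per the labels, cells were plated in triplicate wells and kept for 24 h in vehicle (DMSO) or in 10 nM cortistatin A (CA), a natural steroidal alkaloid that inhibits the Mediator kinases CDK8 and CDK19. There were 3 DMSO and 3 CA samples, each on 1 Affymetrix U133 Plus array. Per the labels' protocols, RNA was isolated with either of 2 kits and then amplified and biotin-labelled from its 3' end. The labels do not say which kit was used for which sample, so the kit could not be examined as a batch.

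The deposited values are log2 intensities per probe set that the authors made by RMA with the affy package, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the probes across arrays and summarises them per probe set, and it compresses large fold changes. The versions of RMA and affy, and which arrays were normalized together, are not given in the sources used here. The 6 arrays had nearly the same distribution, with medians of 5.59 to 5.62. On arrays there is no sequencing depth, and the number of arrays limits the precision.

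The table held 54675 probe sets, of which 62 were control probe sets. The platform annotation listed 42892 of the others, 41091 with 1 gene symbol and 1801 with several, and 11721 were unnamed here. Of the probe sets with 1 symbol, 41037 (99.9%) matched a gene table of assembly GRCh38.p14 by Entrez number. Symbols were updated through it, which changed the names of 2 genes of the lists, and the order of genes along chromosomes was taken from the same table. Probe sets with several symbols named no gene. Each gene was represented by the probe set with the highest mean log2 over the 6 arrays, which left 19775 genes. No filter on level was applied.

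CA was compared with DMSO by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on all 6 arrays, 2-sided, without covariates. The p-values were adjusted by Benjamini-Hochberg over the 19775 genes, and a gene was called at an adjusted p under 0.05. Adjusted p-values of single genes are from this fit. The p-values measure only the spread between these samples, which were wells of 1 experiment as far as the labels say, and that spread may be technical. RNA quality and hybridisation controls were compared by an exact permutation test, 2-sided, for which 3 against 3 arrays cannot give a p under 0.1.

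There were 30 gene lists, each tested by limma's camera with its preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. Members were also counted over all genes tested and adjusted over the list alone. The lists covered the Mediator kinase module, core Mediator, the genes known to have been followed in the study, haematopoietic transcription factors, MLL-fusion targets and stem or progenitor genes. They also covered markers of monocytes and macrophages, granulocytes, megakaryocytes, erythroid cells, T and NK cells, B cells, and epithelial or stromal cells. Further lists held interferon response, MHC class II, NF-kB, G2/M, S phase, p53 and CDK inhibitor, BCL2 family, MYC and ribosome biogenesis genes. The rest held FLT3-STAT5 targets, ERK feedback and immediate early genes, cholesterol and lipid synthesis, hypoxia and glycolysis, Wnt, Notch and TGF-beta targets, the integrated stress and unfolded protein responses, heat shock, adhesion and migration, and reference genes. Some genes are in more than 1 list.

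The groups, the test, the lists, the rule for named genes and all alternatives were fixed before the data were examined. The rule named every measured gene of the kinase module and of the study's list, the 12 called genes with the largest rise and the 12 with the largest fall, and of every other list up to 4 called members with the largest change. The 12 rises and 12 falls were taken among genes whose CA and DMSO values did not overlap and whose mean log2 was at least 6 in the higher group. Where a list has other called members that are named, the text says that they were chosen after their values were seen.

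Alternatives were the mean of all probe sets of a gene, the probe set of largest variance, and leaving out probe sets ending in _x_at or _s_at, which can match several genes or transcripts. Others were a mean log2 of at least 5 or 6, centring arrays on their medians or on the reference genes, a second quantile normalization, an intensity trend with robust moderation, array weights, a replicate block, and leaving out each array in turn. Thresholds were varied to adjusted p under 0.01 or 0.1, at least 1.2-fold or 1.5-fold, and Holm adjustment, and a test per probe set was run. Lists were also tested with an estimated correlation, on ranks, and with fry, which asks whether a list's genes move on balance in 1 direction and compares them with no other genes. With an estimated correlation, camera also refers its statistic to the residual degrees of freedom of the 6 arrays instead of the number of genes. Its p-values then rise even without added correlation between genes.

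The test was checked on simulated values of the 19775 genes with the spread of these arrays, 50 genes changed by each size. It recovered 28% of changes of 0.25 on the log2 scale, 68% of 0.5, 98% of 1 and 100% of 2, with 7 unchanged genes called. In the simulation 154 genes were called in all, against 2202 in the data. With fewer changed genes the adjustment is stricter, so these shares do not give the recovery in the real comparison and may understate it. Of the 30 lists, camera called 0 in simulated data with no change, and it called the heat shock list alone when that list was shifted by 0.3 (adjusted p = 1.21e-23). Apart from the genes followed in the study, the lists called in the data had smaller medians, of 0.06 to 0.17 in size. Shifts of that size were not simulated. The simulated genes were drawn independently of each other, so this check cannot show how camera behaves on lists of correlated genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.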

Results

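RNA from 6 samples of MOLM-14 leukaemia cells, 3 kept for 24 h in DMSO and 3 in 10 nM CA, was hybridised to 1 array each. CA inhibits CDK8 and CDK19, the kinases of the Mediator complex that links transcription factors to RNA polymerase II, and the comparison asks which transcripts change when these kinases are inhibited. Arrays of the same group correlated across probe sets at r = 0.998 in each pair, and arrays of different groups at 0.996 to 0.997. Probe sets are not independent replicates. The median absolute difference between arrays of a group was 0.0702 to 0.0777 on the log2 scale, against 0.104 to 0.113 between groups. The 3' minus 5' signal of the GAPDH control, a measure of RNA integrity, was 0.38 ± 0.02 in DMSO and 0.48 ± 0.05 in CA (SD, n = 3; exact permutation p = 0.1, the smallest possible). The same measure for ACTB was 2.27 ± 0.13 and 2.38 ± 0.07 (exact p = 0.3), and the hybridisation controls were at 11.23 ± 0.06 and 11.26 ± 0.03 (exact p = 0.5).

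After CA, the interferon-inducible chemokine CXCL10 rose 6.94-fold, from 7.26 ± 0.12 to 10.06 ± 0.07 (log2, SD, n = 3; log2 change 2.79, SE 0.07, adjusted p = 2.26e-05). S100A9, a calcium-binding protein of myeloid cells, rose 3.59-fold, from 7.64 ± 0.04 to 9.48 ± 0.04. RGS18, a regulator of G-protein signalling in blood cells, fell 3.48-fold, from 7.05 ± 0.19 to 5.25 ± 0.14 (log2 change -1.80, SE 0.11, adjusted p = 2.92e-04). The fractalkine receptor CX3CR1 fell 2.37-fold, from 9.59 ± 0.05 to 8.35 ± 0.04. In all, 1314 genes were higher and 888 lower among the 19775 tested.

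Beside CXCL10 and S100A9, the largest rises were those of TRDV3, a T cell receptor delta segment (2.77), LTB, the cytokine lymphotoxin beta (2.04), GAS1, a growth arrest-specific membrane protein (2.01), and DTX4, a ubiquitin ligase of the Deltex family (2.00). GBP5 (1.99) and GBP2 (1.82) encode interferon-inducible guanylate-binding proteins, CXCL11 (1.72) a chemokine that shares a receptor with CXCL10, and RASD1 (1.95) a Ras-related protein induced by dexamethasone. HES1 (1.70) is a transcriptional repressor downstream of Notch, and CARINH (1.69) a long noncoding RNA next to IRF1. The largest falls after RGS18 were those of PKIB, an inhibitor of protein kinase A (-1.64), the scavenger receptor CD36 (-1.49), HSD11B1, which regenerates active glucocorticoid (-1.33), the adaptor FYB1 (-1.28) and CX3CR1 (-1.25). AQP3, a water and glycerol channel, changed by -1.22, ADA2, a secreted adenosine deaminase, by -1.12, C11orf21 by -1.11, the myeloid nuclear antigen MNDA by -1.09, the transcription factor TFEC by -1.09 and the chemokine CCL5 by -1.06. In these genes the 3 CA values did not overlap the 3 DMSO values, and adjusted p ranged up to 0.00124 (HSD11B1). TRDV3 rested on 1 of 2 probe sets, LTB on 1 of 2, GAS1 on 1 of 3, HES1 on 2 of 3, C11orf21 on 1 of 2, and FYB1 and CD36 on 3 of 5 each. In DMSO, TRDV3 was at 3.57 ± 0.24 (SD, n = 3), below the lower quartile of the arrays (4.12 ± 0.01), so that the size and rank of its rise are uncertain. Without probe sets ending in _x_at or _s_at, TRDV3 (0.10, adjusted p = 0.374), LTB (0.13, 0.403), GAS1 (0.12, 0.416) and HES1 (0.01, 0.965) were not called, while FYB1 and CD36 were.

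**Figure D1:**
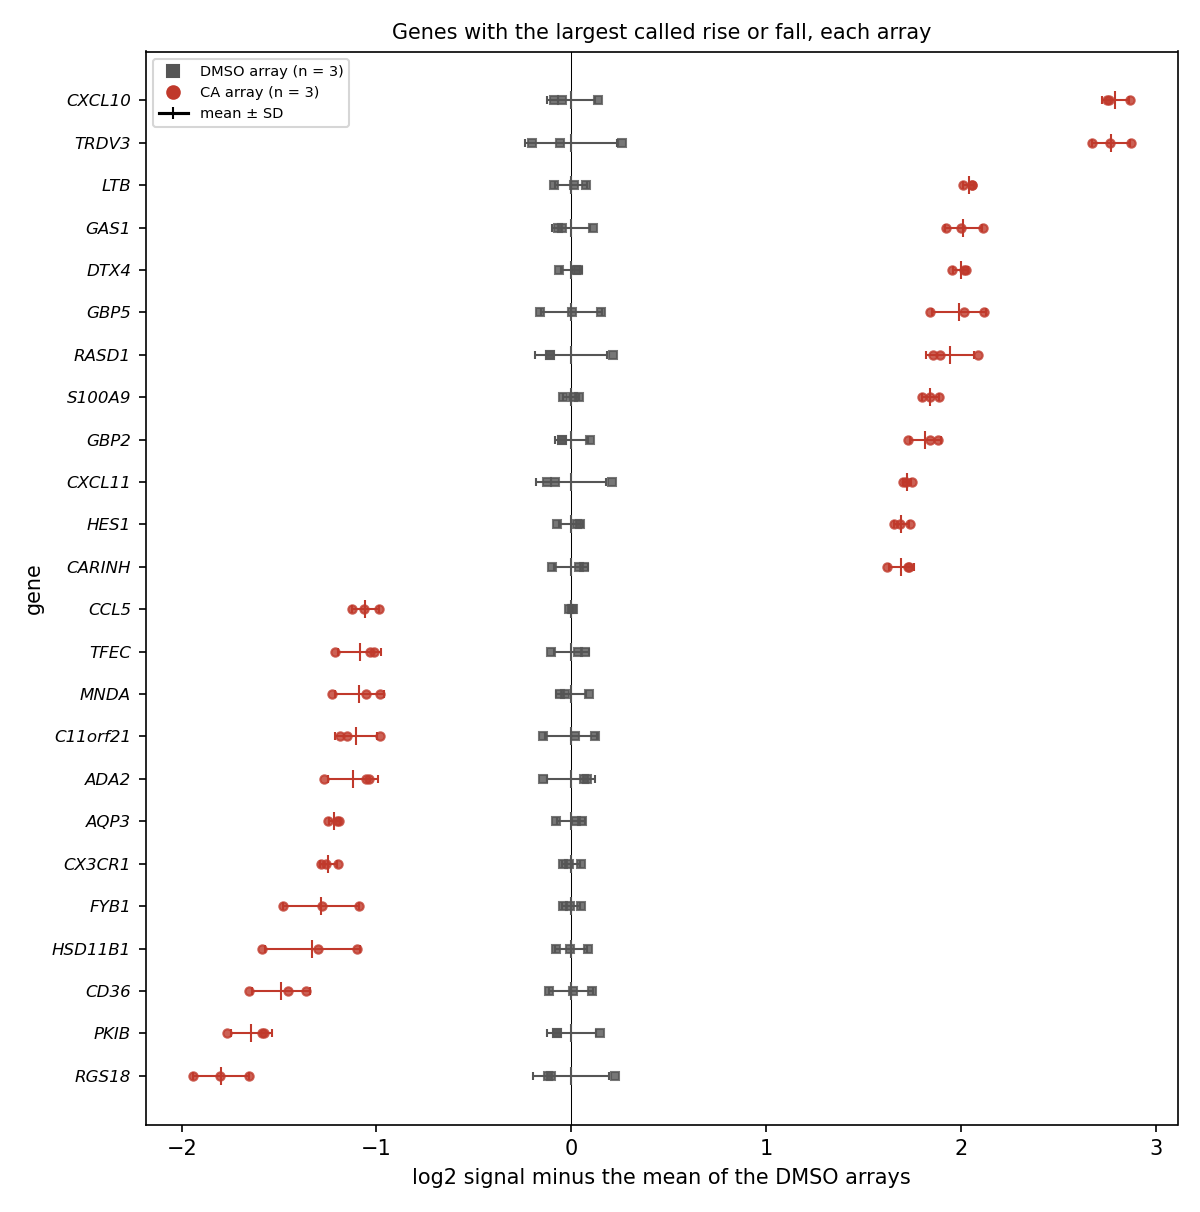
Log2 value of each array minus the DMSO mean (horizontal axis) for the 12 genes with the largest rise and the 12 with the largest fall after CA; points are arrays, and bars give the mean and SD of each group (n = 3). CXCL10 has the largest rise, at 2.79, and RGS18 the largest fall, at -1.80, and the groups do not overlap in any of the 24 genes.

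Most changes were smaller than these. The median called rise was 0.30 and the median called fall 0.27 in size on the log2 scale, and 62 genes rose and 18 fell by at least 2-fold. The groups did not overlap in 6291 genes (31.8%), where chance gives 10%. Higher genes made up 59.7% of the calls, and 74.8% with arrays centred on the reference genes. With any 1 of the 6 arrays left out (DMSO replicate 1, 2 or 3, CA replicate 1, 2 or 3), 1173 to 1331 genes were called in place of 2202. Among the genes named by the rule, at least 1 other probe set pointed the opposite way, uncalled, for CDK19, MED12, MED8, RUNX2, KLF2, SOX4, PAX5, EPOR, HLA-DOB, SOCS1, SKIL, CCNB2, CCNE1, HSPA4, IDI1 and HPRT1. Genes chosen after their values were seen were not checked in this way.

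Of the 6 genes known to have been followed in the study, 4 rose and 0 fell, both over all genes and adjusted over the list alone. IRF1, an interferon regulatory factor, rose 2.99-fold, from 8.25 ± 0.08 to 9.83 ± 0.00 (SD, n = 3; log2 change 1.58, SE 0.05, adjusted p = 3.15e-05). IRF8, a myeloid interferon regulatory factor, rose 1.52-fold (0.60), the cyclin CCNA1 1.46-fold (0.54) and ETV6, an ETS repressor, 1.38-fold (0.47). CEBPA, a myeloid transcription factor, was at -0.01 (95% confidence interval -0.10 to 0.08, adjusted p = 0.939) and the GATA cofactor ZFPM1 at -0.00 (-0.13 to 0.12, adjusted p = 0.977). The list was called higher (camera adjusted p = 1.16e-04), with an adjusted p = 0.110 with an estimated correlation. It is not independent evidence of a direction, since the study chose these genes.

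Of the 7 measured genes of the inhibited kinase module, 1 rose and 0 fell, likewise adjusted over the list alone, and the list was not called (camera adjusted p = 0.997). MED13L, a subunit that joins the module to Mediator, rose 1.18-fold (0.24, adjusted p = 0.0194). That call was lost with each array except DMSO replicate 2 left out, where adjusted p was 0.0617 to 0.0758. MED13L was called on 1 of its 5 probe sets. It was uncalled on the mean of all probe sets (adjusted p = 0.0644) and on that of largest variance (0.375). The kinases CDK8 and CDK19 were at 0.06 (95% confidence interval -0.04 to 0.16) and -0.02 (-0.10 to 0.07), their cyclin CCNC at 0.01, MED13 at -0.06, MED12 at -0.08 and MED12L at -0.15, all uncalled. In core Mediator, 5 of 24 genes rose and 0 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.573). These were MED9 (0.61), MED8 (0.23), MED19 (0.19), MED20 (0.17) and MED17 (0.17), the last chosen after its value was seen. Leaving out any 1 array left 1 or 2 called. The calls of MED19 and MED20 were lost with each array left out (adjusted p of 0.0716 to 0.136), and that of MED8 with each except CA replicate 1 (0.0833 to 0.108).

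**Figure D2:**
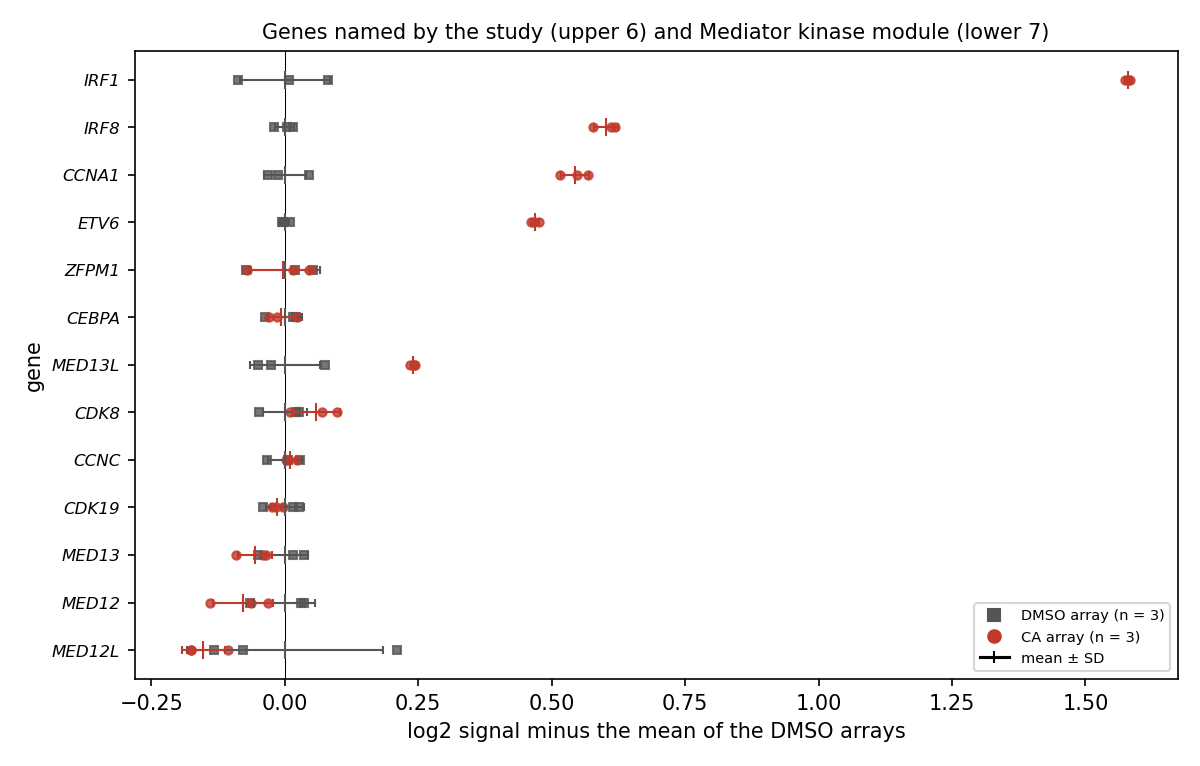
Log2 value of each array minus the DMSO mean (horizontal axis) for the 6 genes followed in the study (upper group) and the 7 genes of the Mediator kinase module (lower group); points are arrays, and bars give the mean and SD of each group (n = 3). IRF1, IRF8, CCNA1 and ETV6 lie to the right of DMSO after CA, while CEBPA and ZFPM1 lie at -0.01 and -0.00.

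Haematopoietic transcription factors and targets of MLL fusions rose more often than they fell. Of 38 measured transcription factors, 15 rose and 4 fell (16 and 4 adjusted over the list alone; median 0.06). PRDM1, a repressor that drives terminal differentiation of lymphoid and myeloid cells, rose 2.68-fold (1.42) and was called on 1 of its 3 probe sets. BHLHE40 rose 2.04-fold (1.03), ETS2 1.92-fold (0.94) and the Kruppel-like factor KLF2 1.62-fold (0.69). Without probe sets ending in _x_at or _s_at, 6 rose and 2 fell of 31 measured, and KLF2 was at -0.14 (adjusted p = 0.430). The factors that fell were NFE2 (-0.57) and, chosen after their values were seen, LYL1 (-0.37), GFI1 (-0.33) and CEBPB (-0.26). The list was called higher by camera (adjusted p = 6.04e-04), with adjusted p = 0.174 with an estimated correlation. Of the 25 MLL-fusion targets listed, 9 were not measured. Among the 16 measured, 9 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.17), and 5 or 6 rose with any 1 array left out. They included RUNX2 (0.58), the MEIS1 partner PBX3 (0.36), GNAQ (0.29) and the cell-cycle kinase CDK6 (0.26). On the mean of all probe sets 5 rose, and RUNX2 was at 0.14 (adjusted p = 0.0723) and CDK6 at 0.23 (0.103). CDK6 was also uncalled on its probe set of largest variance (0.17, adjusted p = 0.641). This list was also called higher (camera adjusted p = 2.19e-04; adjusted p = 0.110 with an estimated correlation). Among 14 stem and progenitor genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.953), with a median of -0.06, a mean of 0.02 and a test direction of higher. SOX4 rose 1.54-fold (0.62) and NPR3 1.19-fold (0.25), and the stem cell factor receptor KIT fell 1.22-fold (-0.29). NPR3 lost its call with each array except DMSO replicate 3 left out (adjusted p of 0.0503 to 0.0684), and KIT with each except CA replicate 3 (0.0535 to 0.0810).

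Among called genes of the monocyte and macrophage list and of the granulocyte list, more fell than rose. Of 32 measured monocyte and macrophage genes, 9 fell and 2 rose (12 and 2 adjusted over the list alone; median -0.16). The genes that rose were S100A9 (1.84) and S100A8 (1.19), which together encode calprotectin, abundant in monocytes and neutrophils. CD36 (-1.49) and MNDA (-1.09) fell the most. Camera called the list lower (adjusted p = 1.16e-04), with adjusted p = 0.110 with an estimated correlation. Of 23 granulocyte genes, 4 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.07). The serine proteases PRTN3 (-1.02) and ELANE (-0.39), their inactive relative AZU1 (-0.90) and the ribonuclease RNASE2 (-0.41) fell, while CTSG, a protease of the same granules chosen after its value was seen, was called higher (0.15), a call lost with each array left out. This list was called lower (camera adjusted p = 0.0135; adjusted p = 0.251 with an estimated correlation), and its adjusted p was 0.0502 without DMSO replicate 3 and 0.0865 on ranks.

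Lists of other cell types held few called genes and none was called by camera on all 6 arrays. Of 21 megakaryocyte and platelet genes, 1 rose and 1 fell, F2R (0.34), the thrombin receptor, and the transcription factor NFE2 (-0.57), likewise adjusted over the list alone (adjusted p = 0.827). F2R was at 0.02 without probe sets ending in _x_at or _s_at (adjusted p = 0.942). Of 14 erythroid genes, 1 rose, the erythropoietin receptor EPOR (0.37), and 0 fell, likewise adjusted over the list alone (camera adjusted p = 0.953; median -0.02, mean 0.01, test direction lower). Without DMSO replicate 1, 2 or 3 or CA replicate 3, EPOR had an adjusted p of 0.0628 to 0.102. On the mean of all probe sets EPOR was at 0.11 (adjusted p = 0.358), PAX5, a B-lineage transcription factor, at 0.20 (0.0607) and F2R at 0.18 (0.115). Of 17 T and NK cell genes, 1 rose, the interleukin-7 receptor IL7R (0.98), and 1 fell, the cytotoxic granule gene NKG7 (-0.52) (2 and 1 adjusted over the list alone; adjusted p = 0.856). Of 12 B cell genes, 1 rose, PAX5 (0.42), and 0 fell, likewise adjusted over the list alone (adjusted p = 0.953; median -0.02, mean 0.02, test direction higher), and 1 fell without CA replicate 1. Of 15 epithelial and stromal genes, 2 rose and 0 fell, likewise adjusted over the list alone (adjusted p = 0.227), but without CA replicate 2 camera called the list higher (adjusted p = 0.0375). These were PECAM1 (0.33), an adhesion molecule also of leukocytes and platelets that was uncalled on its probe set of largest variance (adjusted p = 0.383), and the keratin KRT18 (0.26), whose call was lost with each array left out (adjusted p of 0.0503 to 0.102).

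Interferon response genes changed in both directions. Of 43 measured, 13 rose and 7 fell (13 and 8 adjusted over the list alone; median 0.04), and the list was not called by camera (adjusted p = 0.137). Among genes with a mean log2 of at least 6, camera called the list higher (adjusted p = 0.00734). With any 1 array left out, 8 to 11 interferon response genes rose and 2 to 4 fell. CXCL10 (2.79), the guanylate-binding protein genes GBP2 (1.82) and GBP1 (0.90), and the peptide transporter TAP1 (0.65) rose the most. The GBP genes are close paralogs, and probes may be shared between them. In DMSO, GBP1 was at 4.33 ± 0.07, near the lower quartile of the arrays (4.12), so the size of its rise is uncertain. Of 27 NF-kB and inflammatory genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0784). Camera called this list higher among genes with a mean log2 of at least 5 (adjusted p = 0.0429) or 6 (0.00563) and without CA replicate 2 (0.0310). TNF rose 3.19-fold (1.68), IER3, an immediate early gene, 1.89-fold (0.92) and TNFAIP3, an inhibitor of NF-kB signalling, 1.77-fold (0.83). These 3 genes were measured only by probe sets ending in _s_at. Without probe sets of that kind or ending in _x_at, 0 of 19 measured members rose and 1 fell by limma. Camera's direction for the list then turned lower (adjusted p = 0.999), at a median of 0.00462. CCL5 fell 2.08-fold (-1.06), and IL1RN, the interleukin-1 receptor antagonist, chosen after its value was seen, fell (-0.77). Of 12 MHC class II genes, 3 rose and 0 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.253): HLA-DMB (0.49), the class II transactivator CIITA (0.33) and HLA-DOB (0.27). On the mean of all probe sets CIITA was at 0.14 (adjusted p = 0.0995) and HLA-DOB at 0.11 (0.406). CIITA lost its call with each array except DMSO replicate 2 left out (adjusted p of 0.0577 to 0.0820). Of 17 adhesion and migration genes, 7 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.482). Of the 16 measured without probe sets ending in _x_at or _s_at, 4 rose and 4 fell. The chemokine receptors CCR1 (0.65) and CCR2 (0.59) and the ectoenzyme CD38 (0.62) rose. CX3CR1 (-1.25) fell, as did the leukocyte integrin chain ITGB2 (-0.46), ICAM3 (-0.29) and SELPLG (-0.22), the last 3 chosen after their values were seen.

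The mitotic genes that changed fell by small amounts. Of 30 G2/M genes, 4 fell and 0 rose (8 and 0 adjusted over the list alone; median -0.09). With an intensity trend and robust moderation 14 fell and 1 rose, and at a mean log2 of at least 6, 10 fell and 1 rose. The mitotic kinesins KIF20A (-0.36) and CENPE (-0.26) fell, as did the cyclin CCNB2 (-0.19) and DLGAP5 (-0.18), a spindle protein. With any 1 array left out 2 fell, since CCNB2 and DLGAP5 had adjusted p of 0.0522 to 0.106. Camera called the list lower (adjusted p = 1.16e-04), with adjusted p = 0.170 with an estimated correlation. Of 26 S phase genes, 4 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.127). The cyclin CCNE1 (0.27), RFC4 (0.17) and CDC6 (0.16) rose, CCNE2 (-0.25) fell, and the list also held MCM2 (0.15) and TK1 (-0.15), chosen after their values were seen. In fits with any 1 array left out, 1 rose and at most 1 fell. CCNE1 was at 0.10 on the mean of all probe sets (adjusted p = 0.228). RFC4 and CDC6 lost their calls with each array left out (adjusted p of 0.0572 to 0.124), and CCNE2 without CA replicate 1, 2 or 3 (0.0570 to 0.0675).

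Of 21 p53 targets and CDK inhibitors, 5 rose and 2 fell, likewise adjusted over the list alone (camera adjusted p = 0.447). TP53I3, a p53-induced oxidoreductase, rose (0.68), as did CDKN1B, which encodes the CDK inhibitor p27 (0.63). CDKN1A, the p53 target that encodes the CDK inhibitor p21, fell 1.36-fold (-0.45), and the p53 target ZMAT3 fell 1.26-fold (-0.33). The others that rose were PMAIP1 (0.25) and, chosen after their values were seen, the death receptors FAS (0.20) and TNFRSF10B (0.18). Of 15 BCL2 family genes, 4 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.150). The antiapoptotic BCL2A1 rose 2.46-fold (1.30), as did the proapoptotic BCL2L11 (1.10), PMAIP1 and BID (0.18, chosen after its value was seen), and the antiapoptotic BCL2L2 fell (-0.20). Without probe sets ending in _x_at or _s_at, the only kind for TP53I3 and CDKN1A, 1 of 15 measured genes of the first list rose and 0 fell by limma, with ZMAT3 at an adjusted p of 0.0512. With any 1 array left out, 2 to 4 genes of the first list rose and 1 fell, and 2 or 3 of the second rose and 0 fell by limma. ZMAT3 and BCL2L2 lost their calls with each array left out (adjusted p of 0.0565 to 0.110), and PMAIP1 without DMSO replicate 1 or 2 or CA replicate 1 or 3 (0.0501 to 0.0656).

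Of 14 FLT3-STAT5 targets, 7 rose and 1 fell (7 and 2 adjusted over the list alone; median 0.17). LTB (2.04), the differentiation inhibitor ID1 (0.87), the feedback inhibitor SOCS1 (0.71) and the kinase PIM1 (0.48) rose, and the cyclin CCND2, chosen after its value was seen, fell (-0.27). On the mean of all probe sets SOCS1 was at 0.18 (adjusted p = 0.168). The list was called higher (camera adjusted p = 0.00147; adjusted p = 0.114 with an estimated correlation). Of 26 ERK feedback and immediate early genes, 6 rose and 2 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.482). The ERK phosphatases DUSP6 (0.69) and DUSP5 (0.55) and the transcription factor EGR3 (0.73) rose. EGR3 was at 4.30 ± 0.15 in DMSO, near the lower quartile of the arrays (4.12), so the size of its rise is uncertain. The immediate early factors EGR1 (-0.70, called on 1 of its 3 probe sets) and, chosen after its value was seen, FOS (-0.38) fell. Of 18 Wnt, Notch and TGF-beta targets, 4 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.360). The Notch targets HES1 (1.70) and NRARP (0.30), the SMAD repressor SKIL (0.28) and SMAD7 (0.27), chosen after its value was seen, rose, and ID2 fell (-0.65). Without DMSO replicate 1, 2 members fell, and without probe sets ending in _x_at or _s_at, 2 rose and 0 fell of 15 by limma, with HES1 at 0.01 (adjusted p = 0.965). SKIL was at 0.11 on the mean of all probe sets (adjusted p = 0.187).

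Of 9 heat shock genes, 3 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.14): the cochaperones BAG3 (0.54) and DNAJB1 (0.26), and HSPA4 (0.20). The list was called higher (camera adjusted p = 6.04e-04; adjusted p = 0.114 with an estimated correlation), but not on the probe set of largest variance (adjusted p = 0.0902). Without probe sets ending in _x_at or _s_at, camera's direction for the list turned lower (adjusted p = 0.999), at a median of 1.83e-04. By limma 0 of 5 members were then called, with HSPA4 at -0.09. Of 21 MYC and ribosome biogenesis genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.07). The nucleolar proteins NOLC1 (0.22) and NOP2 (0.21) rose and the polyamine enzyme ODC1 fell (-0.25), and 0 or 1 rose with any 1 array left out by limma. The list was called higher (camera adjusted p = 0.00570; adjusted p = 0.143 with an estimated correlation), but not on the mean of all probe sets (adjusted p = 0.123) or the probe set of largest variance (0.489). Of 20 cholesterol and lipid synthesis genes, 4 rose and 0 fell (10 and 1 adjusted over the list alone; median 0.11): SQLE (0.24), HMGCS1 (0.22), DHCR7 (0.19) and IDI1 (0.18). That list was called higher (camera adjusted p = 0.00572; adjusted p = 0.134 with an estimated correlation), but not on the probe set of largest variance (adjusted p = 0.206). By limma, 0 of the 20 members were called on the mean of all probe sets, and 0 or 1 with any 1 array left out. HSPA4, NOP2, SQLE, HMGCS1 and IDI1 lost their calls with each array left out (adjusted p of 0.0512 to 0.130). DHCR7 did so with each except CA replicate 2 (0.0863 or more), and NOLC1 without CA replicate 2 or 3 (0.0531 and 0.0532).

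Of 18 stress response genes, 4 rose and 4 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.856; median -0.02, mean 0.00, test direction lower). The unfolded protein response genes HERPUD1 (0.48), XBP1 (0.43) and, chosen after its value was seen, DNAJB9 (0.30) rose, as did the lipoprotein receptor VLDLR (0.50). The cystine transporter SLC7A11 (-0.73) and, chosen after their values were seen, the amino acid response genes ASNS (-0.30), TRIB3 (-0.24) and ATF4 (-0.19) fell. When any 1 array was left out, 4 rose and 2 to 4 fell. XBP1 was uncalled on its probe set of largest variance (adjusted p = 0.0655), and HERPUD1 was at 0.06 without probe sets ending in _x_at or _s_at (adjusted p = 0.620). Of 21 hypoxia and glycolysis genes, 5 rose and 2 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.924). NDRG1 (0.39) and the glucose transporter SLC2A3 (0.35) rose, as did ANKRD37 (0.28), DDIT4 (0.26) and SLC2A1 (0.17), chosen after their values were seen, and BNIP3L (-0.58), a mitophagy receptor, and MXI1 (-0.41), a MYC antagonist, fell. With any 1 array left out, 1 or 2 rose and 2 fell, and SLC2A3 lost its call without DMSO replicate 1 or CA replicate 1, 2 or 3 (adjusted p of 0.0568 to 0.0883). Of 9 reference genes, 0 rose and 1 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.482; median 0.00, mean -0.04, test direction lower). HPRT1 was at -0.21 (-0.03 on the mean of all probe sets, adjusted p = 0.724), and without DMSO replicate 3 or CA replicate 3 its adjusted p was 0.0586 and 0.0539.

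**Figure D3:**
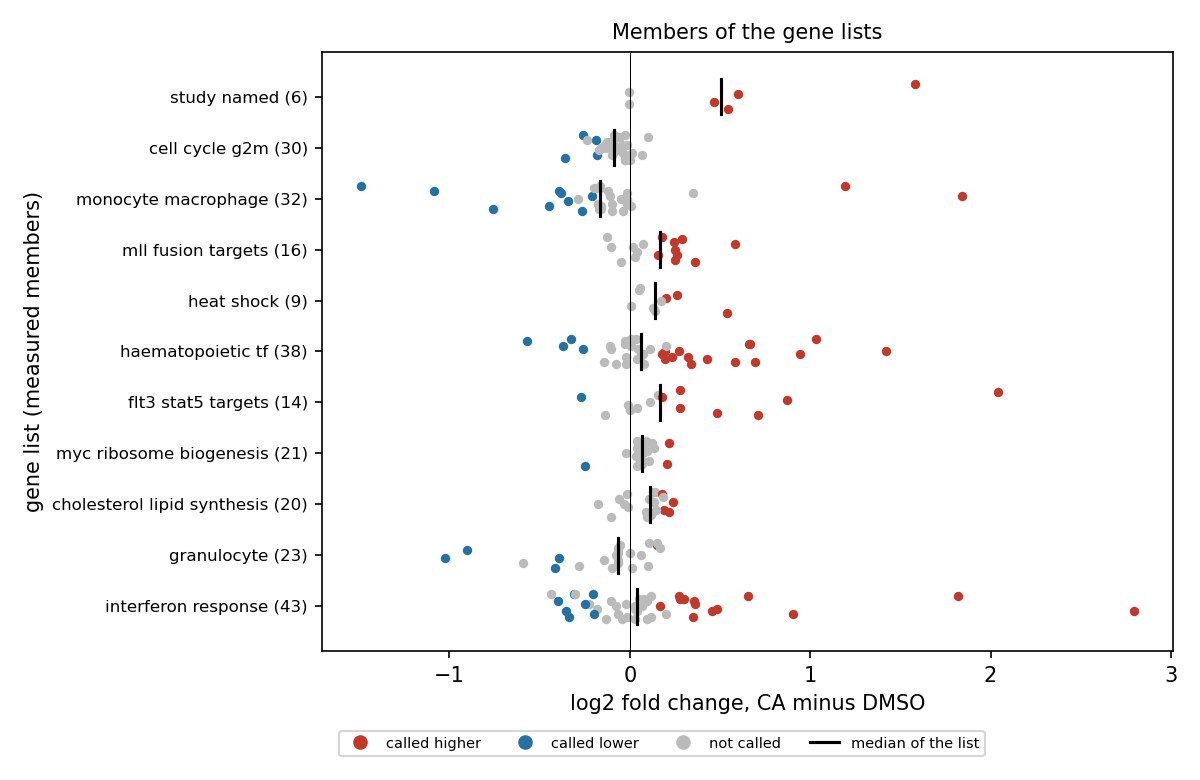
Log2 fold change of CA against DMSO (horizontal axis) for each measured gene of the 10 lists that camera called and of the interferon response list; red points are genes called higher, blue points genes called lower, grey points genes not called, and the black line is the list's median. The medians run from -0.16 for monocyte and macrophage genes to 0.51 for the genes followed in the study.

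Camera called 10 of the 30 lists, 7 higher and 3 lower, and 0 of these calls held with an estimated correlation, while fry, which does not compare a list with other genes, called 19. Because the estimated setting has little power with 3 arrays per group, these losses do not separate correlation between genes from the size of the experiment. Without probe sets ending in _x_at or _s_at, the lists of FLT3-STAT5 targets (0.0859), cholesterol and lipid synthesis (0.139), granulocyte (0.174) and MYC and ribosome biogenesis genes (0.196) were not called. Members that then rose and fell were 7 and 5 of 34 interferon response genes, 2 and 5 of 28 monocyte and macrophage genes, 3 and 0 of 10 FLT3-STAT5 targets, 1 and 2 of 13 hypoxia genes, 1 and 1 of 18 S phase genes, 1 and 0 of 20 core Mediator genes, 2 and 2 of 14 stress response genes, 1 and 0 of 15 cholesterol genes, and 0 and 0 of 15 megakaryocyte genes. With an intensity trend and robust moderation, 10 cholesterol and lipid synthesis, 8 heat shock and 7 MYC and ribosome biogenesis genes rose. The GAPDH control differed between the groups as given above, and the RNA isolation kit of each sample was not known.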

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

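Of the tests in this part, the count of other splits of the samples was chosen only after the result was seen.

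Probe sets outside the comparison also carried differences between the groups. Among the 11721 probe sets with no gene listed, 178 were called higher and 134 lower after CA by limma (2.66%), and among the 1801 with several genes listed, 63 were higher and 49 lower (6.22%). Control probe sets for 28S ribosomal RNA, which are not part of the gene test, were also higher after CA. The middle one was at 11.07 ± 0.04 in DMSO and 11.47 ± 0.02 in CA, a difference of 0.404, and the 5' one at 12.60 ± 0.12 and 12.86 ± 0.11, a difference of 0.257 (SD, n = 3; exact permutation p = 0.1 for both, the smallest possible). For 18S the difference was 0.03 (exact p = 0.7). No explanation of the ribosomal signal was tested.

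The 3' minus 5' difference of the GAPDH control was 0.10 higher after CA, with all 3 CA arrays above all 3 DMSO arrays (exact permutation p = 0.1, the smallest possible), so RNA integrity might contribute to the called genes. If it did, genes should follow the GAPDH difference within each group in the direction of their change. Of the 2202 called genes, 51.3% had a within-group slope of that sign, against a median of 50.4% and a 95th percentile of 55.2% over 100 random within-group directions. The share lies between the values that would have decided, so RNA integrity and CA cannot be told apart as sources of small changes with 3 arrays per group.

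The 10 ways of splitting the 6 arrays into 3 against 3 are too few for a share under 0.05. The real split gave 2202 called genes by limma, and the highest of the others gave 0, with only 1 split, the real one, reaching 2202. In the real split 5004 genes had an unadjusted p under 0.05 by limma, and in the others 598 to 906. Each of the other splits mixes CA and DMSO arrays within its groups. The difference between the treatments then adds to the spread within groups and lowers the counts. These counts, and the 0 calls, are therefore no measure of what chance alone would give.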

How the results depend on the processing

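No test in this part was chosen after the result was seen. For each result that changed, the cause was not tested, except where fewer arrays or genes or another threshold by construction change the count. Signal over background limits dim genes, and a mean log2 of at least 5 or 6 left 13838 or 10997 of the 19775 genes. Of the list results under alternatives, 528 kept direction and side of the threshold, 20 were weaker, 14 stronger and 34 reversed, and of the named genes 1781, 219, 0 and 22. All 18 values of the RNA and hybridisation controls with 1 array left out moved by less than 1 SD. In groups of so few arrays, leaving out 1 array cannot move such a value by 1 SD, whatever the data. The stability of these controls was therefore not tested. No called gene among those named by the rule turned its sign under another scaling or with an array left out. With an array left out none could, since the CA and DMSO values of these genes did not overlap. Centring moves all genes by the same amount, which was smaller than any of these changes. Neither result therefore shows that the signs are stable. Under any scaling the median of all genes was at most 0.0347 (log2). Of 113 calls of genes named by the rule, 87 held with every array left out in turn. These genes were mostly chosen for the size of their change. Of all 2202 calls, 1130 to 1270 were shared with each fit that left out 1 array.

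The count of genes called higher, lower and in either direction was 1314, 888 and 2202. It was 770, 566 and 1336 without probe sets ending in _x_at or _s_at (1250 genes shared with the 2202), and 841, 570 and 1411 on the probe set of largest variance (1201 shared). With a mean log2 of at least 6, 1539 were lower and 3453 called in all. Centring on the reference genes gave 581 lower, and an intensity trend with robust moderation 2119, 1695 and 3814. The threshold gave 573, 312 and 885 at adjusted p under 0.01, 1432 lower at 0.1, 795, 454 and 1249 with at least 1.2-fold, 206, 81 and 287 with at least 1.5-fold, and 109, 30 and 139 by Holm. With 1 array left out in turn, 721 to 848 were higher, 435 to 495 lower and 1173 to 1331 called in all. The mean of all probe sets, a mean log2 of at least 5, median centring, a second quantile normalization, array weights and the test per probe set kept the count of all calls within 1.5 times.

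The replicate numbers share only a number between the groups. Deviations of same-numbered arrays correlated at 0.0226, 0.0299 and 0.0245, and 0 of the 3 pairs matched best with their own number. With the replicate block, 716 genes were higher, 402 lower and 1118 called in all. The stem and progenitor list then turned lower (adjusted p = 0.875).

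With an estimated correlation, camera's adjusted p was 0.170 for G2/M, 0.174 for haematopoietic transcription factors, 0.110 for MLL-fusion targets, 0.110 for monocyte and macrophage genes and 0.110 for the genes followed in the study. The interferon response list was called higher at a mean log2 of at least 6 (0.00734) and by fry (6.23e-04), while over its alternatives the adjusted p ranged from 6.23e-04 to 0.803. The 5 called primary lists were called with each array left out.

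Reversals of lists concerned lists that were not called, except heat shock. They are changes in the direction of the list test, which the median did not always share. Without probe sets ending in _x_at or _s_at, adhesion (0.994), heat shock (0.999), hypoxia (0.672) and NF-kB (0.999) turned lower and the kinase module (0.999) higher. B cell genes turned lower on the mean of probe sets (0.945), the largest variance (0.896), a mean log2 of at least 5 (0.950) and ranks (0.944). The kinase module turned higher at a mean log2 of at least 6 (0.877), with median centring (0.971), reference centring (0.920), array weights (0.957) and fry (0.563). Stem and progenitor genes turned lower at a mean log2 of at least 5 (0.967), with reference centring (0.995) and on ranks (0.865). Erythroid genes turned higher at a mean log2 of at least 5 (0.950) and with a second quantile normalization (0.968). Megakaryocyte genes turned higher on the largest variance (0.726) and stress genes with fry (0.520). With 1 array left out, adjusted p ranged from 0.669 to 0.970 for B cell, 0.801 to 0.994 for erythroid, 0.767 to 0.994 for kinase module, 0.667 to 0.937 for stem and progenitor, and 0.616 to 0.984 for T and NK cell genes, each with a change of direction.

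Among genes named by the rule, log2 changes reversed without probe sets ending in _x_at or _s_at for IDI1 (-0.15), MED8 (-0.0759), KLF2 (-0.14), HSPA4 (-0.0923) and HLA-DOB (-0.0414). On the probe set of largest variance they reversed for MED12 (0.0420), CCNB2 (0.11), IDI1 (-0.15) and HLA-DOB (-0.0414). The uncalled genes near 0 turned sign with scaling: ZFPM1 (0.00581 with median centring, 9.28e-04 with quantile normalization, 0.0345 with reference centring), CEBPA (0.00256 with median and 0.0312 with reference centring) and CDK19 (0.0230 with reference centring). With 1 array left out, the CCNC log2 fold change ranged from -0.0065 to 0.0244, the ZFPM1 log2 fold change from -0.0399 to 0.0301 and the CEBPA log2 fold change from -0.0256 to 0.00441.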

Other observations

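Of the tests in this part, the test of dim probe sets was chosen only after the result was seen.

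Metallothionein genes, which encode metal-binding proteins, rose together, and this family was chosen after its values were seen. All 8 measured members were called higher, from MT1E at 0.82 and MT1M at 0.84 to MT1X at 1.02 and MT1G at 1.07, with MT2A at 0.96, MT1F at 0.98, MT1H at 0.95 and MT1HL1 at 0.85. Of the 8, 7 rested on probe sets ending in _x_at, which can match several members of this family, so that the number of members that rose is uncertain. Without those probe sets 2 members were measured, MT1M at 0.84 (adjusted p = 0.0106) and MT1G at 0.16 (adjusted p = 0.465). Both were dim, at a mean log2 of 4.40 for MT1M and 4.0 for MT1G. In DMSO, MT1M was at 3.98, below the lower quartile of the arrays (4.12), so the size of its rise is uncertain.

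Interferon response genes were called in both directions, 13 higher and 7 lower. Among the 27 members with a mean log2 of at least 6, 12 of the 13 rises and 4 of the 7 falls remained. Dim probe sets alone therefore do not account for both directions, though the falls below that level may rest on them. Nor does the choice of probe set alone, since on the mean of all probe sets 12 rose and 6 fell. A hypothesis is that genes of the IRF1 and interferon-gamma type rose while genes of the type I interferon response fell, examined on 2 further lists whose values had not been looked at. The median of 26 measured IRF1-type genes was 0.12, at percentile 100 of 10000 random lists matched on level (95% range -0.06 to 0.05), with 10 called higher (10 adjusted over the list alone) and 1 lower, CASP1 (-0.22), and camera p = 0.00532 (0.0837 with an estimated correlation). The median of 26 type I genes was -0.01, at percentile 28.4 (range -0.05 to 0.06), with 1 higher, TRIM14 (0.19), and 6 lower (likewise adjusted over the list alone; camera p = 0.210), so a rise of the first group may be part of the pattern, a fall of the second stays open, and the medians differed by 0.13 (permutation p over genes 0.0444, genes not being independent).

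Among the IRF1-type genes CXCL9 (0.58), WARS1 (0.49), IL15RA (0.43) and LAP3 (0.30) rose, and among the type I genes DDX60L (-0.63), DDX60 (-0.32), IFITM2 (-0.28), EIF2AK2 (-0.27), PLSCR1 (-0.25) and IFITM3 (-0.22) fell. These genes were named after their values were seen.

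Neighbouring genes were often called in the same direction, such as IRF1 and CARINH (1.58 and 1.69), UGDH and SMIM14 (1.03 and 1.18), and HCST and TYROBP (-0.88 and -0.76), pairs that were noticed before the test. Of 19712 adjacent pairs of measured genes, 219 were called in the same direction, where shuffles of the calls within bins of level gave a mean of 139.1 (permutation p = 1e-04, the smallest that 10000 shuffles can give), and 110 were called in opposite directions. Without overlapping genes, symbols that share a root and probe sets ending in _s_at or _x_at, 81 of 7888 pairs remained, against a mean of 46.3 (permutation p = 1e-04, again the smallest). Pairs of these kinds therefore do not account for all of the excess. The root is only the first letters of a symbol, so related neighbours with unlike symbols, such as PRTN3 and ELANE, were kept. Their part in the remaining excess was not tested. On simulated calls the count was 146 against 139.0 with shuffled calls and 245 against 149.3 with 100 planted pairs. A hypothesis is that some neighbours may respond together to CA, while transcription running through from 1 gene into the next was not tested and stays open.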
